A study of Mus musculus with 6 samples.

How the data were processed

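Total RNA was profiled from microglia of Fmr1 knockout mouse cerebellum, 3 libraries from saline-treated and 3 from poly(I:C)-injected mice. Per the labels' protocols, animals were perfused, cerebella were homogenised, myelin was removed on Percoll, and cells were enriched with magnetic beads against CD11b, a surface protein that microglia share with monocytes, neutrophils and other macrophages. Full-length cDNA was amplified with a SMARTer kit and made into libraries with Nextera XT, per the labels' protocols. These steps amplify by PCR, and the labels mention no molecular identifiers, so counts are of reads and not of molecules.

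The authors deposited a table of raw read counts per gene symbol with 1 column per library, neither normalised nor pooled. The tools named are fastp, HISAT2 and HTSeq with genome build GRCm39, per the submitters' processing notes, and their versions, settings and annotation are not given in the sources used here. The strand setting is not given either, and Nextera XT does not mark strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Close paralogs can share or lose reads depending on the counting mode. No row holds unassigned reads, so the share of reads outside genes is unknown. No coordinates are printed, because no annotation of the build was used here.

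From the counts, differences between poly(I:C) and saline were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr within groups, leaving 14727 of 23491, libraries were scaled by TMM, and the quasi-likelihood F test (glmQLFit and glmQLFTest) used all 6 libraries with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are scaled by TMM, and means are given ± SD over 3 libraries. Library totals were between 33710545 and 34899835 counts. Replicates of a group differed by more than counting noise, with a chi-square per gene between 21.2 and 113, so no library was treated as a duplicate.

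Gene lists, 34 in all, were fixed before the data were examined, together with the tests and the rule for named genes. They cover interferon and inflammatory responses, microglial states, metabolism and stress, RNA quality, and markers of other cells in or near the cerebellum. Of 740 list memberships 22 had no row here, which include older or newer symbols of the same gene, and these are not analysed here. The 33 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation and all libraries no list passed, and the type I interferon list had an adjusted p of 0.0705. A list that misses there is undecided rather than shown to be unchanged. Many lists share an adjusted p of 0.904 there, because the Benjamini-Hochberg step can give the same value to lists of neighbouring rank. Named genes were (a) among called genes with a mean of at least 5 CPM, groups that do not overlap, and no predicted or clone name, up to 12 with the largest change in each direction, (b) up to 4 members of each list with the smallest p, and (c) Fmr1, Il17a, Il17ra, Cx3cr1, Itgam, P2ry12 and Tmem119. Genes outside this rule are said to be chosen after their values were seen.

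The alternatives were RLE, upper-quartile and total-count scaling, no filter and a stricter filter of 5 CPM in 3 libraries, limma-voom with sample quality weights, DESeq2 1.42.0, a replicate block, removal of mitochondrial genes, a 1.5-fold threshold with glmTreat, and leaving out each library in turn. Chosen after seeing the data were a fit without saline replicate 1 and poly(I:C) replicate 1, and fits with a choroid plexus or a neutrophil marker score as covariate, and camera with an estimated correlation in the fits that left out libraries. The scripts were tested on simulated data for this comparison, with 14515 genes in the step and 200 of them changed. The test recovered 2% of genes changed 1.5-fold, 34% at 2-fold, 66% at 4-fold and 76% at 8-fold, and 3 of 92 calls were unchanged genes. Most differences under 2-fold would therefore be missed at this spread between libraries. Genes were simulated independently of each other, without shifts shared by many genes of a library, so the share of false calls may not carry over to the real data. The changed genes were picked at random, yet camera called 1 list at its preset correlation and 0 with an estimated correlation.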

Results

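RNA-seq read counts were analysed for microglia purified from the cerebellum of Fmr1 knockout mice, a mouse model of fragile X syndrome. Microglia are the resident macrophages of the brain. The mice had received saline (3 libraries) or an intraperitoneal injection of poly(I:C) (3 libraries), a synthetic double-stranded RNA that mimics a viral infection. The control is called saline in the treatment label and sham in the sample titles, and is called saline here. The saline libraries held 34608620, 34611736 and 34899835 counts, and the poly(I:C) libraries held 33726877, 33710545 and 33781938. At these depths 3 counts corresponded to between 0.0860 and 0.0890 CPM (counts scaled to a common library total) before composition scaling, and intervals and floors from counts cover counting error only. Of 23491 gene symbols, 14727 were tested and 1338 had no count in any library. The labels do not say whether the replicates of a group were separate animals, so the p-values measure the spread between these samples, which may be technical.

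Reads over Fmr1 were present in every library. The saline libraries had 1243, 1336 and 1375 counts and the poly(I:C) libraries 2205, 1484 and 1897. Fmr1 stood at 39.0 ± 1.41 CPM in saline and 53.7 ± 9.42 CPM in poly(I:C) (mean ± SD, n = 3 each). The log2 difference of 0.46 (SE 0.14) did not pass the test in edgeR (adjusted p = 0.167). Without a wild-type group, and without knowing which part of the gene was disrupted, these reads check neither the genotype nor the labels.

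The comparison of poly(I:C) with saline asked how a systemic viral mimic alters the transcripts of cerebellar microglia from mice labelled Fmr1 knockout. Of the 130 higher genes, 36 were in the fixed list of the antiviral type I interferon response and 68 were in no fixed list. Irf7, a transcription factor that amplifies interferon signalling, went from 21.2 ± 6.51 to 331 ± 64.0 CPM (SD, n = 3 each), a 15.7-fold difference. Ifit1, Ifit2, Ifit3 and Ifit3b, interferon-induced genes of antiviral defence, were between 13.7-fold and 20.6-fold higher. Far fewer genes were called lower in the edgeR fit, led by Ddit4, an inhibitor of mTOR signalling, which was 3.78-fold lower. Other tools did not show this imbalance, with 557 higher and 448 lower in DESeq2 and 1268 and 1608 in limma-voom with quality weights.

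In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 130 genes were higher with poly(I:C) and 11 were lower. Of the higher genes, 93 were at least 2-fold higher and 24 at least 8-fold higher, and 62 belonged to a gene list fixed beforehand. In all 141 called genes the CPM values of the 3 saline and 3 poly(I:C) libraries did not overlap. Such separation was seen in 28.4% of all tested genes, against 10% by chance. The number of calls depended on single libraries. Without saline replicate 2, saline replicate 3 or poly(I:C) replicate 3 it dropped to 66, 53 and 51 higher genes and to 2, 0 and 0 lower genes. Without poly(I:C) replicate 1 there were 5 lower genes and without poly(I:C) replicate 2 there were 20. In each of these fits, and without saline replicate 1, all 141 genes kept their direction. Of them, 49 were called in every such fit, all 49 higher with poly(I:C) and 24 of them in the type I interferon list. DESeq2 called 557 genes higher and 448 lower, and limma-voom with quality weights called 1268 higher and 1608 lower, so the share of higher genes fell from 92.2% to 55.4% and 44.1%.

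**Figure D1:**
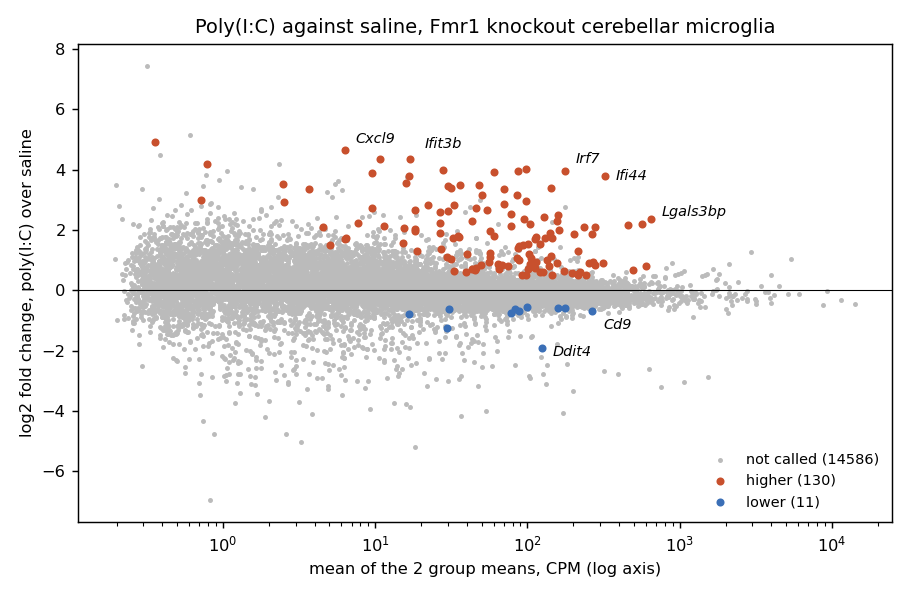
Log2 fold change of poly(I:C) over saline against mean expression for the 14727 tested genes, with the genes past the adjusted p threshold coloured by direction. Cxcl9 lies at 4.64 among the 130 higher genes, and Ddit4 at −1.92 is the lowest of the 11 lower genes.

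Among called genes with a mean of at least 5 CPM, the chemokine gene Cxcl9 had the largest increase, from 0.48 ± 0.35 to 12.1 ± 7.04 CPM, a log2 fold change of 4.64 (SE 0.69, adjusted p = 0.0360). It was followed by Ifit3b, at a log2 fold change of 4.37 (SE 0.29, adjusted p = 0.00108). Saa3, an acute-phase serum amyloid gene, went from 1.01 ± 0.75 to 20.6 ± 5.22 CPM. Cfb, the gene for complement factor B, went from 3.27 ± 1.37 to 52.1 ± 14.9 CPM. Ifi44l rose 16.2-fold, Ifi44 13.8-fold and Phf11a 14.8-fold. Apod, which encodes the lipid carrier apolipoprotein D, went from 2.51 ± 0.75 to 29.4 ± 17.3 CPM. Its highest value, 49.4 CPM, was in poly(I:C) replicate 1, against 19.9 and 18.8 CPM in poly(I:C) replicates 2 and 3. The smallest p-value belonged to Xaf1, an interferon-inducible gene, which went from 22.1 ± 0.82 to 172 ± 7.33 CPM, a log2 fold change of 2.96 (SE 0.08, adjusted p = 4.56e-05). Cxcl9, Saa3, Ifit2 and Apod, which had the largest standard errors of the 12 named genes that rose, were not among the 49 genes called in every fit that left out 1 library. Ifit3 and Ifit3b, the Phf11 genes, the Slfn8 family, the Gbp genes and other close paralogs can share reads, so the split of counts between such copies is uncertain.

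**Figure D2:**
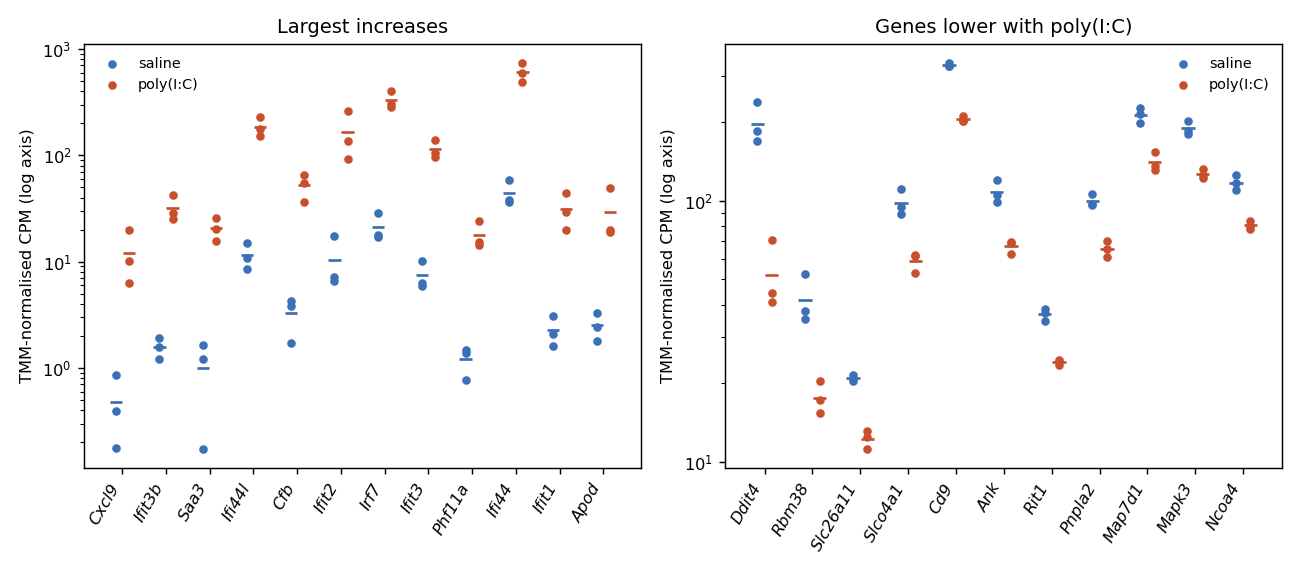
CPM of the named genes in each of the 6 libraries on a log axis, with group means, for the 12 genes with the largest increases and the 11 genes that fell. The saline and poly(I:C) libraries do not overlap for any of these genes, and Irf7 goes from a mean of 21.2 to 331 CPM.

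The type I interferon response list moved together. Of its 44 tested members, 36 were higher and 0 lower over all genes tested, and 43 were higher when adjusted over the list alone. The median log2 fold change was 2.49. Besides the Ifit genes, Rtp4 rose 10.4-fold, Lgals3bp, which encodes a secreted galectin-binding protein, rose 5.13-fold from 211 ± 18.0 to 1081 ± 83.1 CPM, and Slfn8 rose 3.65-fold. The camera test with a preset correlation gave an adjusted p of 1.56e-170. With an estimated correlation the adjusted p was 0.0705, and fry, which asks whether the members move one way on balance, gave an adjusted p of 0.00696. Mx1 and Mx2 were not analysed here.

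The list of interferon gamma targets and MHC class I presentation had 12 of 32 members higher and 0 lower, or 25 higher and 1 lower adjusted over the list alone, with a median log2 fold change of 0.97 (camera adjusted p = 1.46e-33). The adjusted p with an estimated correlation was 0.148. Irgm1 and Igtp, immunity-related GTPases that act against intracellular pathogens, were 3.74-fold and 2.65-fold higher. Gbp3, a guanylate-binding protein gene, was 3.32-fold higher, and the proteasome activator subunit Psme2 went from 48.4 ± 4.01 to 87.3 ± 1.94 CPM. The MHC class II list had no called member among 9, whether over all genes or adjusted over the list alone (camera adjusted p = 0.187, median −0.28). Leaving out saline replicate 2 brought it past the threshold as lower (adjusted p = 0.0123, or adjusted p = 0.770 with an estimated correlation). Its transactivator Ciita had a log2 difference of −0.75 (SE 0.20, adjusted p = 0.151).

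The double-stranded RNA sensing list was also called higher by camera at its preset correlation, though 8 of its members were not called. Of 17 tested members, 9 were higher and 0 lower, or 10 higher and 1 lower adjusted over the list alone, with a median log2 fold change of 1.00 (camera adjusted p = 9.62e-24, adjusted p = 0.0705 with an estimated correlation). Dhx58, a member of the RIG-I-like receptor family, rose 5.78-fold from 22.9 ± 4.30 to 132 ± 4.81 CPM. The RNA-editing deaminase Adar rose 2.49-fold and the RNA-activated kinase Eif2ak2 rose 4.92-fold. Dhx58, Irf7, Eif2ak2 and Zbp1 also belong to the type I interferon list, so these lists are not independent. Without saline replicate 1, and with an estimated correlation, the adjusted p was 0.0366 for the type I interferon list, 0.0442 for the interferon gamma list and 0.0321 for double-stranded RNA sensing, while without any other single library no list passed with an estimated correlation.

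**Figure D3:**
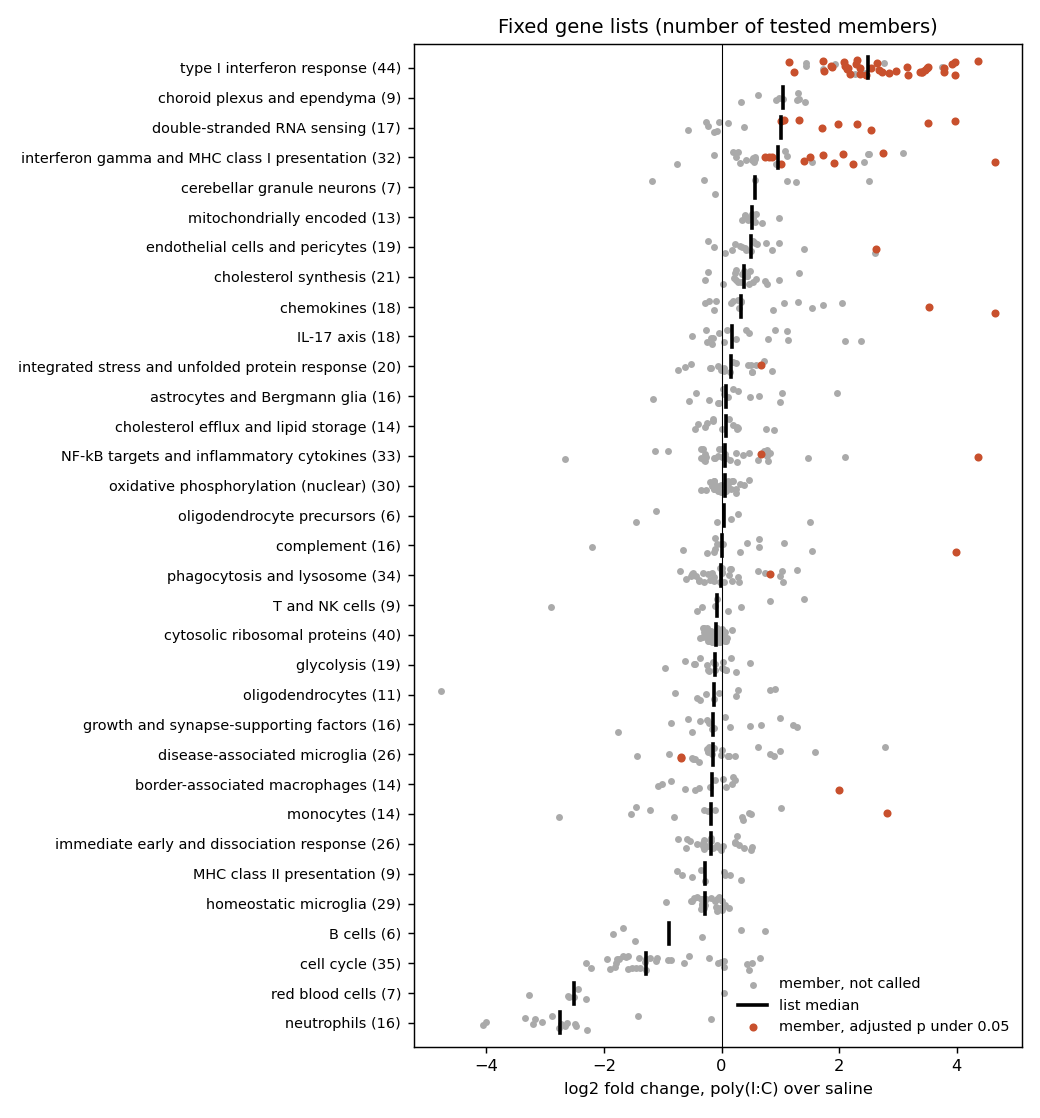
Log2 fold change of poly(I:C) over saline for each member of the 33 tested gene lists, with called members in colour and a bar at each list median. The type I interferon list has a median of 2.49, and the neutrophil list lies lowest with a median of −2.74.

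Of the 11 genes that were lower, 9 belonged to no fixed list. Ddit4 went from 197 ± 36.3 to 52.1 ± 16.4 CPM, a log2 fold change of −1.92 (SE 0.24, adjusted p = 0.0183). Rbm38, an RNA-binding protein gene, was 2.37-fold lower. The others were between 1.46-fold and 1.70-fold lower. Cd9, a tetraspanin gene, had the smallest standard error of the 11, at 0.07 on the log2 scale, and stood at 330 ± 4.25 CPM in saline and 204 ± 5.59 CPM in poly(I:C) (adjusted p = 0.00713). Ank, a transporter gene involved in pyrophosphate export, was 1.61-fold lower. Pnpla2, which encodes the main triglyceride lipase of adipose tissue, was 1.53-fold lower and Ncoa4, a receptor for ferritin breakdown, 1.46-fold lower. The kinase gene Mapk3 was 1.49-fold lower, the Ras-like GTPase gene Rit1 1.53-fold lower, and Map7d1 1.51-fold lower. The transporter genes Slc26a11 and Slco4a1 were 1.70-fold and 1.67-fold lower. None of the 11 was called in every fit that left out 1 library, and without saline replicate 3 or poly(I:C) replicate 3 the count of lower genes was 0, with 1913 and 1831 genes of either direction at an unadjusted p under 0.05.

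The title of the series concerns IL-17A made by cerebellar microglia. Il17a, Il17f and Il22 were not analysed here. Il17b and Il23r, chosen after their values were seen, had 0 counts in all 6 libraries, which allows up to 0.0890 CPM per library. The receptor gene Il17ra was at 296 ± 15.7 CPM in saline and 269 ± 45.6 CPM in poly(I:C), a log2 difference of −0.14 (SE 0.13, adjusted p = 0.547), and the sign turned without poly(I:C) replicate 1. In the IL-17 axis list, 0 of 18 tested members were called over all genes and 1 was higher adjusted over the list alone (camera adjusted p = 0.484, median 0.17). The receptor gene Il17re had the largest difference of the named members, at 0.39 ± 0.08 and 2.05 ± 1.19 CPM (log2 2.37, SE 0.52, adjusted p = 0.115). The shared IL-12 and IL-23 subunit gene Il12b was at 0.36 ± 0.24 and 1.54 ± 0.29 CPM (adjusted p = 0.152). Tgfb1 had a log2 difference of −0.51 (adjusted p = 0.167) and Stat3 of −0.26 (adjusted p = 0.170). Il17re had 10, 16 and 14 counts in saline and 120, 41 and 53 in poly(I:C), and Il12b had 10, 5 and 21 in saline and 51, 44 and 65 in poly(I:C).

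The list of NF-kB targets and inflammatory cytokines was not called, with 2 of 33 members higher, Il18 and Saa3, and 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.309, median 0.06). It passed as higher without saline replicate 1 (adjusted p = 0.0335, or adjusted p = 0.933 with an estimated correlation). Il18 went from 34.7 ± 1.42 to 55.5 ± 1.48 CPM (adjusted p = 0.0146). Tnf, Il1b and Il6, chosen after their values were seen, had log2 differences of 0.72, 0.25 and 0.79 with adjusted p of 0.266, 0.771 and 0.337, and the sign for Il1b turned without saline replicate 2 or poly(I:C) replicate 1. The chemokine list was called higher by camera (adjusted p = 7.04e-05, median 0.33), with an adjusted p of 0.904 with an estimated correlation. Its median was 0.77 without saline replicate 1, 0.16 without saline replicate 2, 0.15 without poly(I:C) replicate 1 and 0.73 without poly(I:C) replicate 2. Only Cxcl9 and Cxcl13 of its 18 members were called, and 5 were higher adjusted over the list alone. Cxcl13, which attracts B cells, went from 0.39 ± 0.05 to 4.58 ± 0.70 CPM (adjusted p = 0.00357). Ccl5 and Ccl12 were 4.14-fold and 3.31-fold higher but missed the threshold (adjusted p = 0.0552 and 0.0604).

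Transcripts that mark resting microglia showed small differences. The homeostatic list had 0 of 29 members called, over all genes or adjusted over the list alone, and a median log2 difference of −0.29. It was called lower by camera (adjusted p = 0.00141), but the adjusted p with an estimated correlation was 0.904, and without poly(I:C) replicate 1 the median was −0.10 and the call was lost (adjusted p = 0.193). Without both saline replicate 1 and poly(I:C) replicate 1 the list was called lower (adjusted p = 0.0243, or adjusted p = 0.916 with an estimated correlation, median −0.17). P2ry12, Tmem119, Cx3cr1 and Itgam had log2 differences of −0.27, −0.30, −0.12 and −0.11, with adjusted p between 0.368 and 0.680. The signs of Cx3cr1 and Itgam turned without poly(I:C) replicate 1. That library also had the highest choroid plexus marker sum, 19094 CPM, and with a choroid plexus score as covariate the adjusted p of the list was 0.458.

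The disease-associated microglia list was not called (camera adjusted p = 0.484). Of its 26 members, Cd9 and Ank were lower and 0 were higher, with 2 in each direction adjusted over the list alone. Axl stood at 128 ± 22.1 and 254 ± 62.3 CPM (adjusted p = 0.106). Spp1 stood at 45.2 ± 2.78 and 310 ± 274 CPM (adjusted p = 0.108), with most of its spread between poly(I:C) libraries. The phagocytosis and lysosome list had 1 of 34 members higher, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.902). That member was Fcgr1, the high-affinity IgG receptor gene, which went from 434 ± 31.2 to 767 ± 62.3 CPM (adjusted p = 0.0185). In the complement list Cfb alone of 16 members was called, over all genes and adjusted over the list alone (camera adjusted p = 0.309). The growth and synapse-supporting factors list had 0 of 16 members called by either adjustment (camera adjusted p = 0.613).

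Among the stress and metabolic lists, the list for the integrated stress and unfolded protein response was called higher by camera (adjusted p = 0.0111, median 0.17). The adjusted p with an estimated correlation was 0.904. Without saline replicate 2 it was 0.180 at the preset correlation and 0.798 with an estimated one. The median was 0.43, 0.083 and 0.11 without saline replicates 1, 2 and 3. The chaperone Pdia6 was the only called member of 20, from 380 ± 33.0 to 606 ± 28.2 CPM (adjusted p = 0.0331), and 7 members were higher and 1 lower adjusted over the list alone. Other chaperones of the endoplasmic reticulum, Hsp90b1 and Pdia4, were 1.65-fold and 1.49-fold higher at adjusted p of 0.0575 and 0.0592. The cholesterol synthesis list was called higher by camera (adjusted p = 1.83e-04, median 0.38) with 0 of 21 members called and 3 higher adjusted over the list alone. Its adjusted p with an estimated correlation was 0.904. Sqle, a rate-limiting enzyme of sterol synthesis, was at 7.37 ± 0.73 and 18.4 ± 7.75 CPM (adjusted p = 0.119). No member was called in the lists for cholesterol efflux (14 tested, camera adjusted p = 0.855), glycolysis (19 tested, 0.309) and nuclear-encoded oxidative phosphorylation (30 tested, 0.877), including adjusted over the list alone. Glycolysis passed as lower without saline replicate 3 (adjusted p = 0.0184, or adjusted p = 0.957 with an estimated correlation).

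The cell cycle list was called lower by camera (adjusted p = 6.12e-04, median −1.29), with 0 of 35 members called over all genes or adjusted over the list alone. The adjusted p with an estimated correlation was 0.904. Cdc20, which activates the anaphase-promoting complex, was 3.72-fold lower with poly(I:C) at an adjusted p of 0.178. Without saline replicate 1 the median moved to −0.25 and the test turned to higher, with an adjusted p of 1.00. With all libraries the call was also lost under the stricter filter (adjusted p = 0.0859), under limma-voom with quality weights (0.167) and with a choroid plexus score as covariate (0.128). A neutrophil score as covariate turned it to higher (0.00902). The neutrophil sums of saline and poly(I:C) libraries did not overlap, so this covariate cannot be well separated from treatment. Saline replicate 1 also had a neutrophil marker sum of 23533 CPM, against 3930 and 3890 CPM in the other saline libraries.

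Lists that report on RNA quality and handling differed between libraries too. The 13 mitochondrially encoded transcripts were called higher as a list by camera (adjusted p = 0.00141, median 0.52) with 0 members called by either adjustment, and the adjusted p with an estimated correlation was 0.904. Without poly(I:C) replicate 1 the median was 0.24, and with a choroid plexus score as covariate the list was not called (adjusted p = 0.242). Their share of counts was 0.81%, 0.75% and 0.66% in saline and 1.49%, 0.82% and 0.99% in poly(I:C). The 40 cytosolic ribosomal protein genes were not called (camera adjusted p = 0.0990), nor was the list of 26 immediate early and dissociation genes (adjusted p = 0.0873), and neither had a called member, although 2 immediate early genes were lower adjusted over the list alone. Ribosomal genes passed as lower without saline replicate 2, saline replicate 3 or poly(I:C) replicate 2 (adjusted p = 0.00462, 0.00350 and 0.00127). Immediate early genes passed as lower without saline replicate 2 or poly(I:C) replicate 1 (adjusted p = 4.72e-05 and 0.00143). With an estimated correlation in the same fits, the adjusted p was between 0.770 and 0.984 for these lists. With no low-count filter both lists passed as lower at the preset correlation (adjusted p = 0.0418 for ribosomal and 0.0397 for immediate early genes).

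Markers of other cells that a CD11b enrichment could carry along varied between libraries. The 16 neutrophil markers were lower as a list (camera adjusted p = 4.93e-07, median −2.74), with 0 members called by either adjustment and an adjusted p of 0.904 with an estimated correlation. Without saline replicate 1 the median was −1.04. Their summed CPM was 23533, 3930 and 3890 in saline and 3389, 1840 and 1870 in poly(I:C). The granule protein genes Camp, Elane and Mpo averaged 365 ± 428, 101 ± 138 and 323 ± 441 CPM in saline, and 35.8 ± 30.5, 6.28 ± 5.71 and 19.5 ± 17.4 CPM in poly(I:C). The 7 red blood cell genes tested were lower as a list (camera adjusted p = 0.00151, median −2.51), with an adjusted p of 0.904 with an estimated correlation. At the preset correlation the adjusted p was 0.0972 without poly(I:C) replicate 2. It was 0.115 under limma-voom and 0.160 with a neutrophil score as covariate, and without saline replicate 2 the median was −1.31. None was called over all genes and 5 were lower adjusted over the list alone. The red cell sum was highest in saline replicate 2, at 448 CPM.

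The 9 choroid plexus and ependyma markers tested were higher as a list (camera adjusted p = 7.67e-04, median 1.05), with 0 called members by either adjustment and an adjusted p of 0.904 with an estimated correlation. Without poly(I:C) replicate 1 the median was 0.62. Their sum was 4017, 8357 and 3921 CPM in saline and 19094, 7569 and 9196 CPM in poly(I:C). Enpp2, a secreted phospholipase gene abundant in choroid plexus, was at 1714 ± 789 and 4173 ± 2540 CPM. The 19 endothelial and pericyte markers were higher as a list (camera adjusted p = 0.00449, median 0.50), with an adjusted p of 0.904 with an estimated correlation. Without saline replicate 1 or poly(I:C) replicate 1 this call was lost (adjusted p = 0.101 and 0.193), as it was under limma-voom (0.168), and a choroid plexus score as covariate turned it to lower (0.00659). The median was 0.32, 1.09 and 0.25 without saline replicates 1, 2 and 3, and 0.086 without poly(I:C) replicate 1. Its called member was Ly6a, a gene that interferon also induces in other cells, at 8.33 ± 3.83 and 51.6 ± 20.8 CPM (adjusted p = 0.0464), and 2 members were higher adjusted over the list alone.

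Border-associated macrophage markers were not called (camera adjusted p = 0.314), with 1 of 14 members higher, and 1 higher and 2 lower adjusted over the list alone. That member was Siglec1, the sialoadhesin gene, which interferon induces in macrophages, from 64.0 ± 14.3 to 257 ± 76.7 CPM (adjusted p = 0.0183). The list passed as lower without saline replicate 2 (adjusted p = 0.0238) or poly(I:C) replicate 1 (adjusted p = 6.88e-04), with adjusted p of 0.798 and 0.934 with an estimated correlation. Monocyte markers were not called (adjusted p = 0.603) and passed as higher without saline replicate 1 (adjusted p = 1.46e-06, or adjusted p = 0.818 with an estimated correlation). Ms4a4c was the only called member of 14, by either adjustment, from 8.15 ± 4.95 to 57.5 ± 17.5 CPM (adjusted p = 0.0460). No member was called, by either adjustment, among T and NK cell (camera adjusted p = 0.840), B cell (0.411), cerebellar granule neuron (0.690), astrocyte and Bergmann glia (0.319), oligodendrocyte (0.613) and oligodendrocyte precursor (0.823) markers. Of these, B cell markers passed as lower without saline replicate 3 (adjusted p = 0.0358) and astrocyte markers as higher without saline replicate 2 (adjusted p = 0.00228). The adjusted p with an estimated correlation was 0.957 and 0.770 in these fits. Purkinje cell and interneuron markers had 4 tested members, too few for the list test, and summed to 64.3 ± 11.7 CPM in saline and 105 ± 41.8 CPM in poly(I:C).

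**Figure D4:**
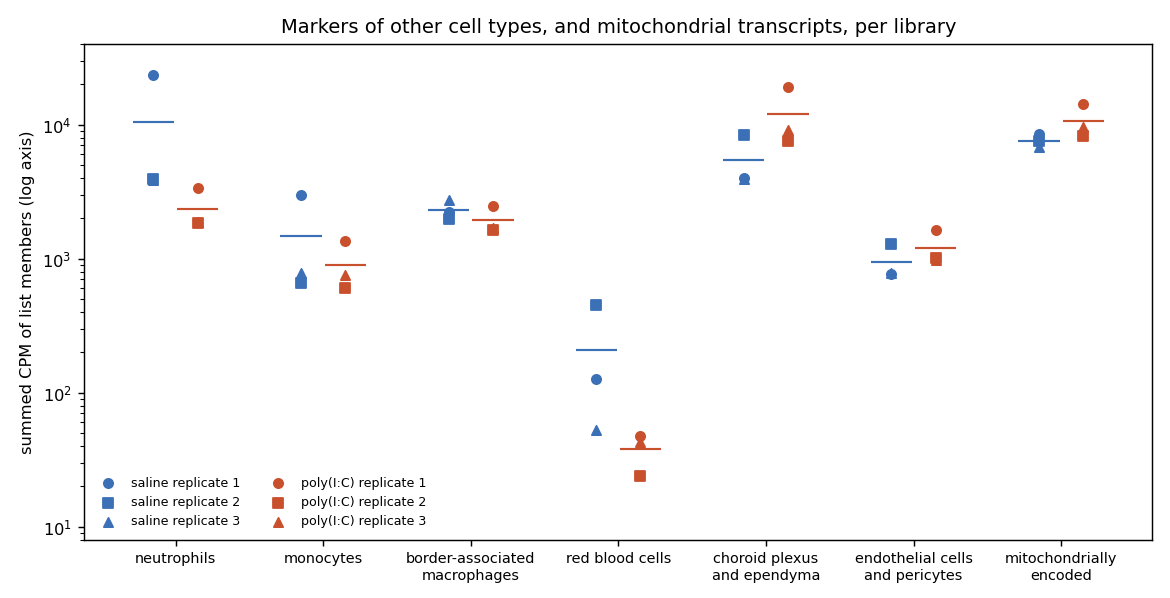
Summed CPM of the markers of other cell types and of the mitochondrially encoded transcripts in each of the 6 libraries, on a log axis, with lines at the group means. Saline replicate 1 has the highest neutrophil sum, 23533 CPM, and poly(I:C) replicate 1 the highest choroid plexus sum, 19094 CPM.

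The counts were repeated without the libraries that held these highest sums, a choice made after seeing the data. Without saline replicate 1 and poly(I:C) replicate 1, 355 genes were higher and 214 lower. The type I interferon list then had 43 of 44 members higher and a median log2 fold change of 2.71. The double-stranded RNA sensing list had 10 of 17 members higher, and the interferon gamma and MHC class I list 23 of 32. Of the 16 neutrophil markers, 15 were lower. With a choroid plexus score as covariate in all 6 libraries, 41 genes were higher and 0 lower, the type I interferon list had 20 members higher and a median log2 fold change of 2.47, and 1096 genes of either direction had an unadjusted p under 0.05. With a neutrophil score, 521 were higher and 522 lower, but that score cannot be well separated from treatment. Without both of those libraries the choroid plexus list was no longer called (adjusted p = 0.186), nor was the endothelial list (adjusted p = 0.566) or the cell cycle list (adjusted p = 0.485). Border-associated macrophage markers were then called lower (adjusted p = 0.0134) and monocyte markers higher (adjusted p = 0.00200), while red blood cell genes (adjusted p = 0.00854), homeostatic microglia (0.0243), mitochondrially encoded transcripts (0.0114), chemokines (5.31e-05), cholesterol synthesis (6.58e-04) and the stress and unfolded protein response (9.75e-04) were called in the direction they had with all libraries. With an estimated correlation in that fit none of these 8 lists passed, at adjusted p between 0.334 and 0.916, and the adjusted p was 0.0631 for the type I interferon and neutrophil lists. Across the lists that were not called, the median, the mean and the test differed in sign in 7, namely disease-associated microglia, phagocytosis, cholesterol efflux, growth factors, monocytes, T and NK cells and oligodendrocyte precursors.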

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

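The fits without both replicates 1 and with a marker score as covariate, and estimated correlations in fits that left out libraries, were chosen after seeing the data. The median log2 fold change of all genes moved by less than 0.1 between scalings (0.01 with TMM, −0.01 with RLE, 0.06 with upper quartile and 0.08 with total counts), and RLE, upper-quartile and total-count scaling kept the counts of genes and lists within 1.5 times. All 141 calls kept their direction in each fit that tested them. No filter gave 18 lower genes. The stricter filter and voom each gave 2 lower lists. Voom called 1268 genes higher and 1608 lower, DESeq2 557 and 448, and glmTreat at 1.5-fold 68 and 1. The replicate block gave 171 higher and 89 lower genes and called complement higher (0.0351), and replicate numbers are not known to pair libraries, since same-number deviations correlated at 0.11, −0.12 and 0.19 and not every library correlated best with its own number. Leaving out 1 library gave 51 to 167 higher and 0 to 20 lower genes, 8 to 10 higher and 3 to 8 lower lists, and an adjusted p of at most 1.32e-75 for the type I interferon list, 0.0335 to 0.978 for NF-kB targets, 1.43e-05 to 0.193 for homeostatic microglia and 0.343 to 0.709 for the IL-17 axis. With an estimated correlation 0 lists were higher and 0 lower, 3 lists had an unadjusted p under 0.05, and the adjusted p was 0.0705 for type I interferon and 0.904 for homeostatic microglia. With 1 library left out and an estimated correlation, the adjusted p for type I interferon was 0.0366, 0.184 and 0.216 without saline replicates 1, 2 and 3, and 0.250, 0.630 and 0.251 without poly(I:C) replicates 1, 2 and 3. For homeostatic microglia, where called at the preset correlation, it was 0.933, 0.798 and 0.957 without saline replicates 1, 2 and 3, and 0.984 and 0.925 without poly(I:C) replicates 2 and 3. Without both replicates 1 these were 0.0631 and 0.916. Fry called 3 lists higher and 0 lower (homeostatic microglia 0.583). Without both replicates 1 there were 355 higher and 214 lower genes. With the choroid plexus score as covariate there were 41 and 0 genes, and homeostatic microglia had 0.458. With the neutrophil score there were 521 and 522 genes, 1 lower list, and NF-kB targets at 7.23e-04. Neutrophil sums did not overlap between saline and poly(I:C), so this fit cannot separate the score well from treatment. Among 50 reversed signs, 47 had no call in either fit (13 lists and 4 genes). Phagocytosis turned higher with upper-quartile (adjusted p 0.905) and total-count scaling (0.901), the stricter filter (0.740), the block (0.677), fry (0.880) and without both replicates 1 (0.444). T and NK cells and granule neurons turned lower with no filter (0.567 each). The stricter filter turned the IL-17 axis lower (0.445) and oligodendrocytes higher (0.889), and voom turned cholesterol efflux higher (0.878). Without both replicates 1, disease-associated microglia (0.229), cholesterol efflux (0.845) and ribosomal proteins (0.119) turned higher, granule neurons (0.433) and oligodendrocyte precursors (0.566) lower, growth factors and T and NK cells kept their direction at 0.0639 and 0.0728, and Il17ra and Itgam had log2 values of 0.0483 and 0.0302. The choroid plexus score turned endothelial cells lower (0.00659) and the neutrophil score turned the cell cycle higher (0.00902). Leaving out 1 library also turned lists whose adjusted p ranged as follows, T and NK cells 0.270 to 0.886, cell cycle 2.75e-09 to 1.00, granule neurons 0.173 to 0.901, cholesterol efflux 0.531 to 0.968, ribosomal proteins 0.00127 to 0.745, disease-associated microglia 0.0571 to 0.811, glycolysis 0.0184 to 1.00, growth factors 0.113 to 0.984, monocytes 1.46e-06 to 0.914, oligodendrocyte precursors 0.0807 to 0.914, oligodendrocytes 0.389 to 0.978, oxidative phosphorylation 0.412 to 0.965 and phagocytosis 0.607 to 0.930. It turned Cx3cr1 (log2 −0.20 to 0.0152), Il17ra (−0.27 to 0.0025), Itgam (−0.17 to 0.0024) and Il1b (−0.0534 to 0.89). The cause of these changes was not tested. Depth limits genes at or under 3 counts per library.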

Other observations

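The family counts, the genes singled out here, the glucocorticoid list and the tests other than the splits of the libraries were chosen after the results were seen. Grouping the tested genes by symbol prefix gave 441 families, and Fisher's exact test (one-sided, Benjamini-Hochberg adjusted) found several with more higher genes than the background of tested genes. Trim genes, many of which encode antiviral ubiquitin ligases, had 8 of 44 members higher (adjusted p = 1.78e-06). Parp genes, which encode ADP-ribosyltransferases, had 4 of 12 (adjusted p = 2.00e-04), and Psme genes, subunits of proteasome activators, had 3 of 6 (adjusted p = 8.31e-04). Families share sequence, and some Trim and Oas members are close copies, as are Psme2 and Psme2b among the called Psme genes. The same signal can therefore be counted repeatedly in a family.

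Other called genes lie outside the named set. The heparan sulfate proteoglycan gene Sdc3 went from 169 ± 40.4 to 752 ± 40.2 CPM (4.45-fold, adjusted p = 0.00281). Il15ra, which presents interleukin 15, was 2.18-fold higher, and Tnfsf10, which encodes the death ligand TRAIL, was 4.11-fold higher (adjusted p = 0.0123). The extracellular matrix gene Comp was 2.47-fold higher. Il15ra and Sdc3 were among the 49 genes called in every fit that left out 1 library. Xist was detected in all 6 libraries, at 1325, 1117 and 1240 CPM in saline and 1962, 1586 and 1823 CPM in poly(I:C) (log2 0.54, adjusted p = 0.123).

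The rise of interferon-stimulated genes may reflect the response of CD11b-positive cells to poly(I:C), and some kinds of carried-along cells were weighed against it. Choroid plexus in poly(I:C) replicate 1 does not account for it, since without both replicates 1 the median log2 fold change of the list was 2.71. Neutrophils do not account for it, since their own list had a median of −2.74 with all libraries and of −1.04 without saline replicate 1. Border-associated macrophages do not either, since their list without Siglec1 had a median of −0.20. Monocytes were not weighed in this way. The median of their list was −0.18 with all libraries, 0.75 without saline replicate 1 and 0.56 without both replicates 1. A contribution from monocytes, and interferon induction within other cells of the preparation, therefore remain open.

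The neutrophil and cell cycle lists were called lower by camera at its preset correlation, but 0 of 16 and 0 of 35 members were called, and the adjusted p was 0.904 for each list with an estimated correlation. Without saline replicate 1 the cell cycle median was −0.25, consistent with dividing immature myeloid cells in that library, where Elane and Mpo reached 261 and 831 CPM. The neutrophil median without it was still −1.04. The camera adjusted p in that fit was 7.04e-06 at the preset correlation, but 0.881 with an estimated correlation. Without both replicates 1, a fit chosen after seeing the data, 15 of the 16 markers were called lower. The neutrophil sums of the other libraries were 3930 and 3890 CPM in saline and 3389, 1840 and 1870 CPM in poly(I:C). These values argue against saline replicate 1 alone as the source of the neutrophil difference, although the test with an estimated correlation did not pass. The tested red cell markers summed to 127 CPM in saline replicate 1 and to 447 CPM in saline replicate 2, which argues against whole blood as the source of the neutrophil excess of replicate 1 over replicate 2. The sum of all red cell markers was 52.9 CPM in saline replicate 3 and 47.6, 23.8 and 42.8 CPM in poly(I:C), so some blood in saline replicate 1 remains open.

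The choroid plexus list was called higher by camera at its preset correlation, but 0 of 9 members were called and the adjusted p was 0.904 with an estimated correlation. The marker sum was highest in poly(I:C) replicate 1. Without that library the median was still 0.62, but the remaining saline and poly(I:C) libraries overlapped, so carry-over into that library alone cannot be told apart from a wider difference. Ttr, the main choroid plexus transcript, was at 2664, 5377 and 2396 CPM in saline and 11106, 4928 and 5604 CPM in poly(I:C). A CD11b enrichment should deplete choroid plexus epithelium, but its transcripts were still present in every library. Dissection differences were not recorded in the labels.

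Ddit4 is induced by glucocorticoids, and Tsc22d3, Sgk1 and Per1, which were picked for their direction, had log2 differences of −0.84, −0.54 and −0.45 that did not pass the test (adjusted p = 0.0806, 0.153 and 0.241). A lower glucocorticoid signal might lower all of these, but Fkbp5, another target, had a log2 difference of 0.63 (SE 0.21, adjusted p = 0.181, unadjusted p = 0.0182), which argues against it as the whole cause although Fkbp5 did not pass the adjusted test. Mt2 and Pdk4 of the same list had log2 differences of 1.12 and 1.84 (adjusted p = 0.162 and 0.195). The list of 16 such genes had 8 below 0 and a median of −0.02.

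With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 130 higher and 11 lower genes, and the highest of the other splits gave 0 in either direction, so 1 of the 10 splits reached each count. For lists the real split gave 9 higher and 4 lower, the highest other gave 17, and 9 and 10 of the 10 splits reached those counts. The share of even counts among genes with 4 to 41 counts was 51.1%, 53.7% and 53.8% in saline and 59.5%, 53.9% and 54.9% in poly(I:C). Even counts were the more common in every library, most of all in poly(I:C) replicate 1, the library with the highest choroid plexus and mitochondrial sums. The window starts at an even count, so even counts are favoured somewhat wherever genes become fewer as counts rise. How much of the excess this explains was not calculated. The higher share in poly(I:C) replicate 1 has no known reason, and low counts and the 3-count floor are less certain in that library.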
